A study of Mus musculus with 6 samples.

How the data were processed

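Whole visceral adipose tissue of male mice, in 6 samples of which 3 were labelled Bmal1WT and 3 Bmal1KO, was profiled by RNA sequencing. Per the labels' protocols, RNA was extracted with a lipid tissue kit, 2 ng of RNA was reverse transcribed from an anchored oligo(dT) primer, the cDNA was amplified and cut with the transposase of the Nextera XT kit, and paired reads of 38 bp were sequenced on a NextSeq500. Such a library does not mark the strand, is amplified from little RNA and carries no molecular identifiers, so counts of a gene and of an overlapping or antisense gene cannot be told apart. Copies from amplification are counted as reads. The floor below covers counting error only, and the bootstrap intervals in the closing section measure the spread between genes.

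The deposited values are counts per gene symbol, made by the authors by aligning reads with STAR 2.7.3a to mm10 and counting with featureCounts, per the submitters' processing notes. The annotation, the strand setting and the treatment of reads with several hits are not given in the sources used here. The table held whole numbers for 55011 gene symbols, of which 20494 had no count in any library, and all 6 columns of counts were used. Totals ran from 6514620 to 9529198 counts per library, so that the floor of 3 counts taken for a gene at 0 corresponded to between 0.315 and 0.461 CPM. Gene coordinates, lengths and GC content were taken from GENCODE M21 (the same assembly, mm10), in which 52830 of the symbols matched exactly 1 gene.

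Groups and replicate numbers came from the sample titles. The labels number the samples but do not state that each came from a separate animal, so p-values measure the spread between these samples. The comparison, its test, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined.

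Counts as deposited were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (13859 of them) and libraries were scaled by TMM. Bmal1KO was set against Bmal1WT without covariates by the quasi-likelihood F-test with robust dispersion, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use the TMM-scaled library sizes, except for genes under the filter, and are given as mean ± SD over 3 libraries. The SE of a log2 fold change is the absolute unshrunken coefficient divided by the square root of the F statistic. The common dispersion was 0.0944.

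For gene groups, 48 lists with 990 entries were written for the cell types that visceral fat can hold, for tissues that can be cut with it, and for metabolic, immune, stress and clock functions. Of the entries, 4 had no match among the gene symbols. Lists with at least 5 tested members, 45 of them, were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it. The lymphatic endothelial list (4 of 9 genes tested), the epididymis and testis list (0 of 27) and the pancreas, liver and gut list (2 of 18) were too short after the filter. For every list, p was also adjusted over the list alone.

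The text names Arntl and Foxp3, then genes that passed the test with no overlap between groups and a mean of at least 1 CPM. Since none passed, the 20 genes of smallest unadjusted p under the same conditions were named, leaving out predicted genes, pseudogenes and antigen receptor segments. For each list described, up to 4 members of smallest p were named, and for the core clock list any tested member. Genes named outside this rule are said to have been chosen after their values were seen.

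The test was tried on simulated data: in each of 10 simulations counts were drawn from the means and sizes of these libraries with 200 genes changed. For Bmal1KO against Bmal1WT, with a median of 13439.5 genes tested, it recovered 26.9% of genes changed 2-fold and 73.8% of genes changed 4-fold, with 9.3 false calls per simulation. A T cell list shifted 2-fold was called in 10 of 10 simulations, and 0 other lists were. Genes were drawn independently of each other there, while the correlation estimated in the data was 0.48 for T cell and 0.81 for ribosomal genes. The simulation therefore cannot show how often camera's preset correlation calls a list falsely in these data. It also gave a gene the same dispersion in both groups. In the data, Bmal1KO replicates correlated at 0.927 to 0.933 in log2 CPM and Bmal1WT replicates at 0.950 to 0.953. The share of changed genes that the test would recover in these data may therefore differ from the simulated one.

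Alternatives were DESeq2's size factors or library size alone for scaling, DESeq2 1.42.0 with its own independent filtering in place of edgeR's filter, limma voom with quality weights on the filtered genes, no filter or at least 1 CPM in 3 libraries, the replicate number as a block, each library left out in turn, a threshold of 0.1, and a prior count of 0.5. Chosen after the data were seen were the removal of an even background from Bmal1KO replicate 1, leaving out Bmal1WT replicate 1 and Bmal1KO replicate 1 together, and the removal of a loess trend on length and GC content. Their effects are given in the closing section.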

Results

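RNA was measured in whole visceral adipose tissue, the fat depot around the abdominal organs, of male C57BL/6 mice. The mice were 30 weeks old and had eaten a low-fat diet for 14 weeks and then a high-fat diet for 16 weeks. The tissue was taken at zeitgeber time 0 h, the start of the light phase. All mice carried a Cre recombinase tied to YFP and driven by Foxp3, the transcription factor of regulatory T cells, and the groups differed in Arntl, the gene for the clock transcription factor BMAL1. Of the 6 libraries, 3 were labelled Bmal1WT and 3 Bmal1KO. The design asks how visceral fat after a high-fat diet differs between mice with and without Bmal1 in Foxp3-expressing cells.

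Total counts per library were 9247131, 8779413 and 9529198 in Bmal1WT replicates 1 to 3 and 6514620, 8678772 and 7731602 in Bmal1KO replicates 1 to 3. Counts of at least 1 were found for 19438, 19009 and 20059 genes in Bmal1WT and for 30019, 20132 and 20145 genes in Bmal1KO. Bmal1KO replicate 1, the shallowest library, thus had counts on the most genes. Bmal1WT replicate 1 carried 6591 counts on 27 genes of epididymis and testis, against 7 to 47 in the other 5 libraries. On the leading principal component of log2 CPM, which held 28.2% of the variance, the Bmal1WT libraries lay between -31.9 and -26.7, Bmal1KO replicate 1 at -4.43, and Bmal1KO replicates 2 and 3 at 39.6 and 52.0. Replicates of a group correlated at 0.927 to 0.953 in log2 CPM over the 13859 genes tested.

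**Figure D1:**
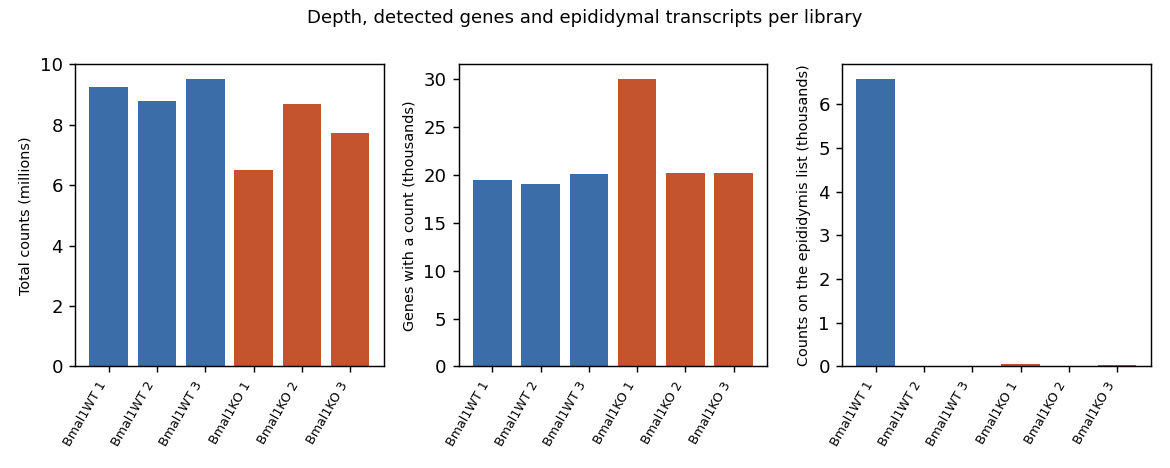
Total counts, genes with at least 1 count, and counts on the 27 genes of the epididymis and testis list, 1 bar for each of the 3 Bmal1WT (blue) and 3 Bmal1KO (orange) libraries. Bmal1KO replicate 1 has counts on 30019 genes against 19009 to 20145 in the others, and Bmal1WT replicate 1 has 6591 counts on the epididymis and testis list.

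The targeted gene Arntl (ENSMUSG00000055116.8, mm10 chromosome 7, 113207465 to 113314126) had 273, 242 and 373 counts in Bmal1WT replicates 1 to 3 and 324, 289 and 314 in Bmal1KO replicates 1 to 3. That was 33.2 ± 6.16 CPM (SD, n = 3) in Bmal1WT and 40.1 ± 8.06 CPM (SD, n = 3) in Bmal1KO, a log2 fold change of 0.27 with SE 0.22 that did not pass edgeR's quasi-likelihood test (adjusted p = 0.719). Since the deletion is aimed at Foxp3-expressing cells and the RNA came from whole tissue, this level is only a weak check of the labels, and no other check of a library's genotype was made. Foxp3 itself (ENSMUSG00000039521.13, mm10 chromosome X, 7573644 to 7595245) had 0 counts in all 3 Bmal1WT libraries and 3, 0 and 2 counts in Bmal1KO replicates 1 to 3. These counts lie at or under the floor of 3 counts per library, so no fold was computed and a difference was not detectable at this depth.

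In Bmal1KO fat, limma's camera with a preset correlation called genes of T cells, mast cells, plasma cells, B cells, macrophages, mesothelium and ribosomes higher as groups. It called genes of adipocytes, endothelium, mural cells and lipid and mitochondrial metabolism lower, and 0 of these groups was called with an estimated correlation (smallest adjusted p = 0.675) or by fry's directional test. T cell genes stood 1.67 log2 units (3.18-fold) above Bmal1WT on average and all 21 of them were higher, while 19 of 20 endothelial genes and 22 of 23 adipocyte genes were lower, by 0.66 and 0.52 log2 units on average. Among single genes, the mast cell proteases Tpsb2 and Mcpt4 and the secreted phagocytosis adaptor Mfge8 had the smallest p. No single gene passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 13859 genes (smallest adjusted p = 0.265). At an unadjusted p under 0.05 there were 1290 genes, 700 higher and 590 lower, where 693 are expected by chance if genes vary independently. Another split of the 6 libraries into 3 and 3 gave 1327. DESeq2, run with its own filter in place of edgeR's, called 60 genes, 36 higher and 24 lower, and limma voom with quality weights called 0, with 1691 at an unadjusted p under 0.05.

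Of the 45 gene lists with at least 5 tested members, limma's camera with a preset correlation of 0.01 called 17, 7 higher and 10 lower in Bmal1KO. With an estimated correlation 0 of the 17 were called, and the smallest adjusted p = 0.675. The directional test of fry, which asks whether a list's genes move 1 way on balance, also called 0. No member of any list passed the test over all genes. The 3 Bmal1KO and 3 Bmal1WT list means did not overlap in 8 lists, 5 of them called, and the smallest 2-sided exact p that 3 libraries against 3 allow is 0.1.

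T cell genes gave the strongest group difference (camera adjusted p = 1.32e-09, adjusted p = 0.675 with an estimated correlation). The list mean was 1.14, 2.02 and 1.85 log2 units above the Bmal1WT mean in Bmal1KO replicates 1 to 3, and the Bmal1WT libraries ranged from -1.11 to 0.75. The list stayed called with each library left out, at means from 1.17 without Bmal1WT replicate 1 to 2.08 without Bmal1WT replicate 2. Bmal1WT replicate 1, at -1.11, thus accounted for part of the mean difference. Of its 21 tested members, 0 passed over all genes and 8 rose with p adjusted over the list alone. Trbc2, a constant segment of the T cell receptor that shares reads with the near-identical Trbc1 and is therefore uncertain, was at 3.83 ± 2.00 CPM (SD, n = 3) in Bmal1WT and 17.4 ± 8.62 CPM in Bmal1KO (log2 fold change 2.19, SE 0.49). Lat, an adaptor of T cell receptor signalling, was at 5.37 ± 2.26 and 16.0 ± 3.00 CPM (1.58, SE 0.37). Cd3e and Cd3g, chains of the receptor complex, had log2 fold changes of 2.44 (SE 0.67) and 2.19 (SE 0.60). Their Bmal1WT means were only 1.985 and 4.55 CPM. In Bmal1WT replicate 1 Cd3e was at 0.228 CPM, under the floor of 0.324 CPM in that library, so its fold is uncertain.

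Markers of regulatory T cells, the cells in which Cre is expressed, were not called as a list (camera adjusted p = 0.115). Of 15 tested members 11 were higher and 4 lower, and 0 passed either over all genes or over the list alone. Tnfrsf18, which encodes the receptor GITR, was at 1.78 ± 1.28 CPM (SD, n = 3) in Bmal1WT and 7.82 ± 2.51 CPM in Bmal1KO (log2 fold change 2.12, SE 0.62). Il2ra, which encodes CD25, the alpha chain of an interleukin receptor, went the other way, from 3.05 ± 0.472 to 1.01 ± 0.451 CPM (-1.59, SE 0.65). Its 3 Bmal1KO counts of 10, 8 and 5 were all under the Bmal1WT counts of 22, 29 and 30. Icos and Gata3 had log2 fold changes of 2.83 (SE 1.11) and 1.58 (SE 0.69). Icos had 0, 11 and 3 counts in Bmal1WT replicates 1 to 3 and 4, 51 and 42 in Bmal1KO. The groups thus overlapped, with counts at or near the floor. Gata3 had 3 counts in Bmal1WT replicate 1, at the floor. All these genes are also expressed by other lymphocytes.

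Mast cell and eosinophil genes were higher by 0.88 log2 units on average, 9 of 10 of them (camera adjusted p = 0.00318, adjusted p = 0.675 with an estimated correlation). All 3 Bmal1KO list means, 0.57 to 1.09, lay above all Bmal1WT means, and the call was lost when Bmal1WT replicate 1 and Bmal1KO replicate 1 were left out together (mean 0.74, adjusted p = 0.0802). Over all genes 0 members passed, and with p adjusted over the list alone 4 rose, each a mast cell protease. The eosinophil members, named after their values were seen, showed no clear rise. Ear2 was lower (log2 fold change -0.53, SE 0.27). Ear1 (0.50, SE 0.71), Ccr3 (0.36, SE 0.67) and Siglecf (0.10, SE 1.10) changed by less than their SE, as did the mast cell receptor Kit (0.23, SE 0.44). Tpsb2 (mm10 chromosome 17, 25366305 to 25369098), whose reads can be split with its near-identical neighbour Tpsab1, was at 33.1 ± 12.9 CPM (SD, n = 3) in Bmal1WT and 119.5 ± 24.2 CPM in Bmal1KO (log2 fold change 1.85, SE 0.28). Mcpt4 (mm10 chromosome 14, 56059629 to 56062313) was at 21.2 ± 6.01 and 66.7 ± 16.9 CPM (1.65, SE 0.26). Cma1 was at 34.0 ± 14.1 and 102 ± 29.7 CPM (1.59, SE 0.33) and Cpa3 at 13.6 ± 6.41 and 38.4 ± 12.6 CPM (1.49, SE 0.36).

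B cell genes (mean 1.06 log2 units, 15 of 16 higher, camera adjusted p = 0.0383) and plasma cell genes (1.52, 11 of 13 higher, camera adjusted p = 0.0241) were called, but their means differed widely between Bmal1KO libraries. With an estimated correlation the B cell list had adjusted p = 0.696 and the plasma cell list adjusted p = 0.675, and 0 members of either passed over all genes or adjusted over the list alone. The B cell mean was 0.85 in Bmal1KO replicate 1, -0.55 in replicate 2 and 2.88 in replicate 3, and the plasma cell means were 2.45, -0.62 and 2.72. The B cell list was no longer called without Bmal1KO replicate 3 (mean 0.14, adjusted p = 0.839) or without Bmal1WT replicate 2 (mean 0.84, adjusted p = 0.108), and its mean was 1.99 without Bmal1KO replicate 2. The plasma cell list was called in 2 of the 6 fits with 1 library left out, with means of 0.91 to 2.61. Ighg2b, an antibody heavy chain in a family of similar genes and so uncertain, was at 6.74 ± 1.36 CPM (SD, n = 3) in Bmal1WT and 117 ± 144 CPM in Bmal1KO, and Bank1, a B cell scaffold protein, at 4.06 ± 0.362 and 17.9 ± 17.6 CPM.

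Macrophage genes were higher by 0.38 log2 units on average, 19 of 21 of them (camera adjusted p = 0.00596, adjusted p = 0.696 with an estimated correlation), with 0 members past the test over all genes or adjusted over the list alone. The list mean was -0.17 in Bmal1KO replicate 1 against 0.67 and 0.65 in replicates 2 and 3. With 1 library left out it ran from 0.205 to 0.66, and the call was lost without Bmal1WT replicate 3 (adjusted p = 0.308) and without Bmal1KO replicate 2 (adjusted p = 0.204) or 3 (adjusted p = 0.209). C1qc, a chain of complement C1q, was at 105 ± 22.0 CPM (SD, n = 3) in Bmal1WT and 210.2 ± 80.2 CPM in Bmal1KO, and the fractalkine receptor Cx3cr1 at 9.15 ± 0.766 and 17.8 ± 4.08 CPM. Mesothelial genes, of the layer that covers the fat, were higher by 0.46 log2 units, 15 of 16 of them (camera adjusted p = 0.00381, adjusted p = 0.675 with an estimated correlation). Without Bmal1WT replicate 3 their mean was 0.21 (adjusted p = 0.228) and without Bmal1KO replicate 2 it was 0.37 (adjusted p = 0.0634), neither called. Over all genes 0 passed, and 1 rose adjusted over the list alone, Upk3b (84.6 ± 22.8 and 153 ± 18.1 CPM, log2 fold change 0.86, SE 0.21). Ribosomal protein genes were higher by 0.35 log2 units, all 51 of them (camera adjusted p = 1.15e-08, adjusted p = 0.696 with an estimated correlation). Of these, 0 passed over all genes or adjusted over the list alone. Their mean was 0.03 in Bmal1KO replicate 1 against 0.58 and 0.45 in replicates 2 and 3. The list stayed called with any 1 library left out, at means from 0.23 without Bmal1KO replicate 2 to 0.51 without replicate 1. Many of these genes have processed pseudogenes that share reads with them.

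Adipocyte genes were lower by 0.52 log2 units on average (camera adjusted p = 3.86e-05, adjusted p = 0.675 with an estimated correlation), and 0 of 23 members passed over all genes or adjusted over the list alone. The list mean was 0.14 in Bmal1KO replicate 1, just above the Bmal1WT range of -0.17 to 0.13. It was -0.70 and -0.998 in replicates 2 and 3. With 1 library left out the list stayed called, with means from -0.85 without Bmal1KO replicate 1 to -0.29 without replicate 3. Pparg, the master transcription factor of fat cells, was at 233 ± 15.8 CPM (SD, n = 3) in Bmal1WT and 145 ± 32.0 CPM in Bmal1KO (log2 fold change -0.68, SE 0.18), and the glycerol channel Aqp7 at 219.5 ± 26.3 and 142 ± 45.5 CPM (-0.63, SE 0.22). Adipokine genes were lower by 0.37 log2 units (10 of 17 lower, camera adjusted p = 0.0346, adjusted p = 0.675 with an estimated correlation, 0 past the test over all genes or adjusted over the list alone), and Rbp4, the retinol binding protein, had a log2 fold change of -0.96 (SE 0.27). The adipokine list was called in 2 of the 6 fits with 1 library left out, with means of -0.61 to -0.21. Without Bmal1KO replicate 1 the gene count changed from 0 to 46 higher and 110 lower, and 9 of the lower genes were on the adipocyte list.

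Lipid and mitochondrial metabolism genes were lower by smaller amounts. Cholesterol synthesis genes were lower by 0.34 log2 units, 18 of 20 of them (camera adjusted p = 0.000135, adjusted p = 0.675 with an estimated correlation). Over all genes 0 passed, and 3 fell with p adjusted over the list alone. The means of all 3 Bmal1KO libraries, -0.52 to -0.20, lay under all Bmal1WT means. Mvk and Pmvk, kinases of the mevalonate pathway, were at 62.0 ± 4.42 and 102 ± 0.212 CPM (SD, n = 3) in Bmal1WT and at 36.3 ± 3.72 and 67.0 ± 6.62 CPM in Bmal1KO. Fatty acid oxidation genes were lower by 0.26 log2 units (22 of 23 lower, camera adjusted p = 0.000135) and genes of the citrate cycle and branched-chain amino acid breakdown by 0.25 (23 of 26, camera adjusted p = 0.000366), both with adjusted p = 0.675 with an estimated correlation. Lipogenesis genes were lower by 0.31 (21 of 24, camera adjusted p = 0.000804), lipolysis genes by 0.29 (20 of 24, camera adjusted p = 0.00443) and oxidative phosphorylation genes by 0.12 (41 of 50, camera adjusted p = 0.00443). With an estimated correlation these had adjusted p = 0.675, 0.675 and 0.696. The oxidative phosphorylation call was lost without Bmal1KO replicate 3 (mean -0.06, adjusted p = 0.16) and after the trend on gene length and GC content was removed (mean -0.05, adjusted p = 0.105). Bmal1KO replicate 1 lay inside the Bmal1WT range for the citrate cycle list (0.02, against -0.08 to 0.06), lipogenesis (-0.03, against -0.09 to 0.10), lipolysis (-0.05, against -0.09 to 0.14) and oxidative phosphorylation (-0.11, against -0.14 to 0.07, with replicate 2 inside as well at 0.00 and replicate 3 at -0.26). With 1 library left out the means ran from -0.45 to -0.20 for lipogenesis, from -0.41 to -0.21 for lipolysis and from -0.39 to -0.17 for the citrate cycle list, each largest without Bmal1KO replicate 1, and these lists stayed called. Adjusted over the list alone 1 lipogenesis gene fell, the desaturase Scd2, and 0 of the other 4 lists. Over all genes 0 of any passed. Cpt2, the inner-membrane carnitine palmitoyltransferase, was at 213 ± 18.8 and 152 ± 7.28 CPM, and Bckdha, of the branched-chain ketoacid dehydrogenase, at 42.3 ± 1.88 and 23.5 ± 8.40 CPM.

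Endothelial genes were lower by 0.66 log2 units on average (camera adjusted p = 4.31e-06, adjusted p = 0.675 with an estimated correlation). They had list means of -0.14 in Bmal1KO replicate 1 and -0.94 and -0.89 in replicates 2 and 3 and a Bmal1WT range of -0.43 to 0.52. With 1 library left out the list stayed called, with means from -0.92 to -0.40, the latter without Bmal1WT replicate 3. Of 20 members 0 passed over all genes, and 1 fell with p adjusted over the list alone: Cldn5, a claudin of endothelial tight junctions, from 246 ± 96.4 CPM (SD, n = 3) to 109 ± 29.4 CPM (log2 fold change -1.18, SE 0.30). Robo4 was at 33.3 ± 12.5 and 13.0 ± 9.09 CPM (-1.37, SE 0.44). Mural and smooth muscle genes were lower by 0.46 log2 units (11 of 12 lower, camera adjusted p = 0.0146, adjusted p = 0.675 with an estimated correlation, 0 past the test over all genes or adjusted over the list alone), among them the pericyte gene Rgs5 at 41.9 ± 13.9 and 22.6 ± 13.8 CPM. The mural list mean was 0.02 in Bmal1KO replicate 1, inside the Bmal1WT range of -0.15 to 0.28. The call was lost without Bmal1KO replicate 2 (mean -0.24, adjusted p = 0.202) and without Bmal1WT replicate 3 (mean -0.32, adjusted p = 0.0567).

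**Figure D2:**
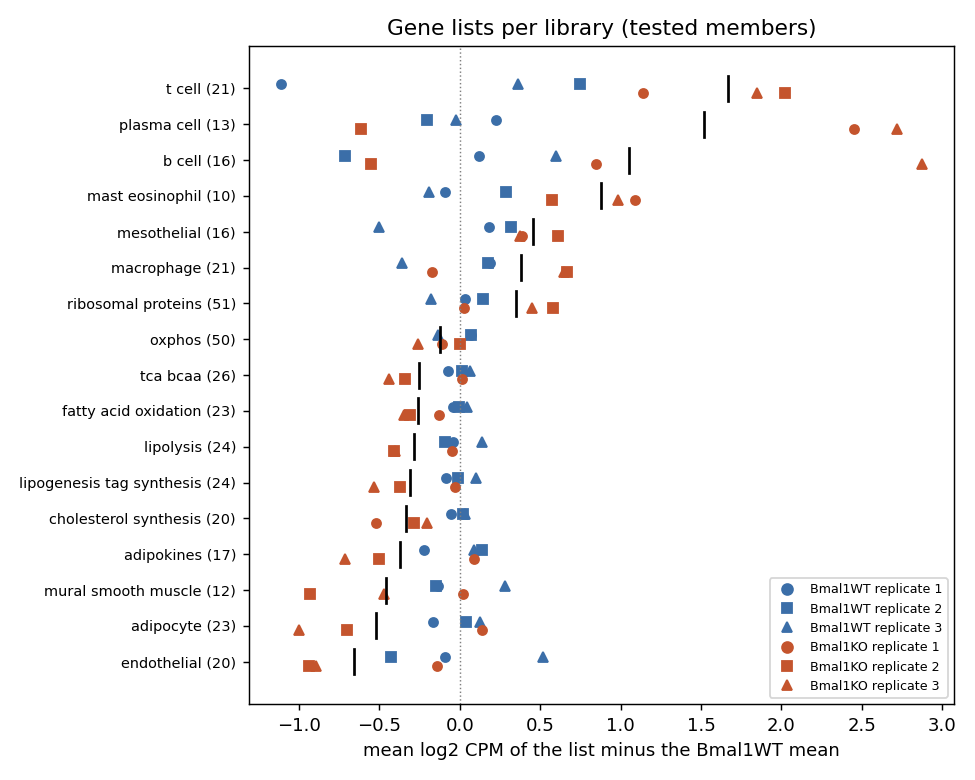
Mean log2 CPM of each of the 17 called gene lists in each library, minus the Bmal1WT mean, with the number of tested members in brackets; blue points are the 3 Bmal1WT and orange points the 3 Bmal1KO libraries, and the black bar is the mean difference. The T cell list separates the groups in all 6 libraries, while on the adipocyte list Bmal1KO replicate 1 stands at 0.14 and replicates 2 and 3 at -0.70 and -0.998.

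The 20 genes of smallest p whose libraries did not overlap between groups were 12 higher and 8 lower, with adjusted p of 0.265 to 0.318, so that none of the 20 passed. Across all tested genes, 2173 (15.7%) had no overlap between the groups, where chance gives 10% for a single gene. Genes vary together between libraries, so the share over all genes can lie away from 10% by chance. It was not computed for other splits of the libraries. Mfge8 (mm10 chromosome 7, 79133768 to 79149060) was at 627 ± 84.2 CPM (SD, n = 3) in Bmal1WT and 1412 ± 137 CPM in Bmal1KO (log2 fold change 1.17, SE 0.18). The matrix genes Fmod (fibromodulin, 66.8 ± 5.78 and 119 ± 4.56 CPM) and Mgp (matrix Gla protein, 490.5 ± 64.9 and 997 ± 197 CPM) were about 1.79-fold and 2.03-fold higher. Lymphocyte and dendritic cell genes among the 20 were Ltb (lymphotoxin beta, log2 fold change 2.35, SE 0.46), Clec9a (a receptor of cross-presenting dendritic cells, 2.53, SE 0.51) and Acap1 (2.75, SE 0.46), at Bmal1WT means of only 4.40, 1.88 and 1.42 CPM. Erap1, which trims peptides for MHC class I, the lamin B receptor Lbr and the bacterial RNA sensor Tlr13 had log2 fold changes of 0.93, 1.33 and 1.11. The lower genes were Gja4 (a connexin of arterial endothelium, -1.79, SE 0.34), Crip2 (-1.09), Ece1 (endothelin-converting enzyme, 117 ± 10.3 and 58.8 ± 15.5 CPM), Rasd1 (-0.99), Scd2 (-0.99), Grwd1 (-0.94), Cers4 (a ceramide synthase, -0.87) and Retsat (retinol saturase, -0.84, SE 0.15). DESeq2 called all 20 of these genes in the same direction, and limma voom called 0. Both used the counts from which the 20 were picked, so the DESeq2 calls are no independent evidence.

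**Figure D3:**
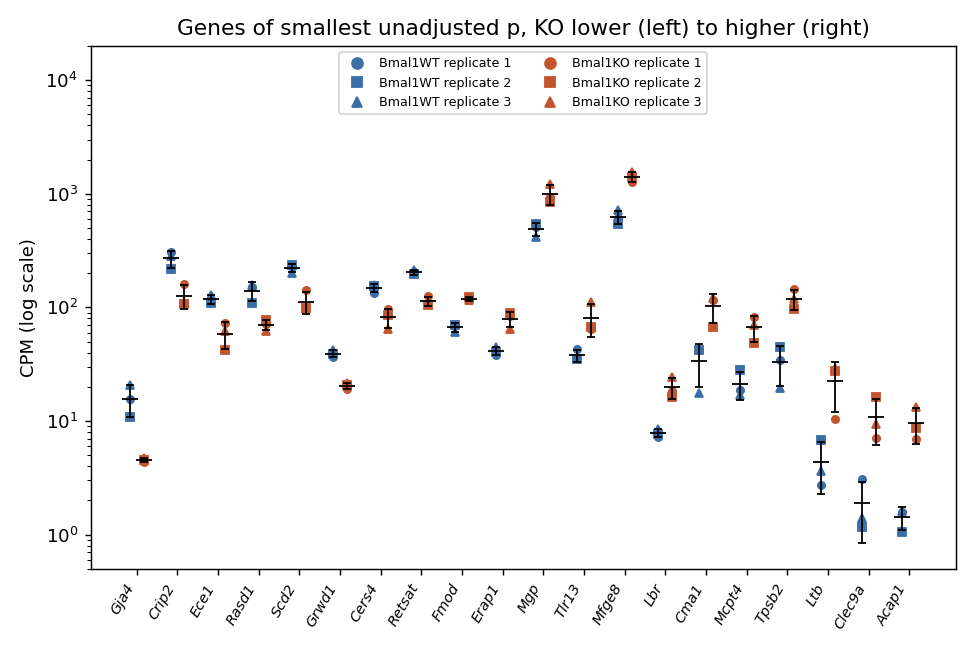
CPM on a log axis of the 20 genes of smallest unadjusted p, ordered from the largest fall to the largest rise in Bmal1KO, with each of the 3 Bmal1WT (blue) and 3 Bmal1KO (orange) libraries as a point and the mean ± SD in black. The libraries of the groups do not overlap for any of the 20, which was a condition for naming them, and Mfge8 is the most abundant, at 627 and 1412 CPM.

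Genes of the circadian clock were not called as a list (18 tested, camera adjusted p = 0.764), and 0 passed over all genes or adjusted over the list alone. The list's test and its mean of 0.16 pointed up while its median was -0.04. By fry's mixed test, which asks whether genes change in either direction, the list had adjusted p = 0.0221. Npas2, a paralog of Clock, was at 1.53 ± 1.05 CPM (SD, n = 3) in Bmal1WT and 4.92 ± 1.03 CPM in Bmal1KO (log2 fold change 1.68, SE 0.68), and Nr1d2, a nuclear receptor of the clock, at 2.14 ± 0.607 and 4.70 ± 1.29 CPM (1.13, SE 0.52). Nfil3, a repressor of D-box genes, was at 13.4 ± 3.32 and 7.83 ± 2.14 CPM (-0.77, SE 0.34), Per1 had a log2 fold change of 0.67 (SE 0.31), and Clock and Rora had log2 fold changes of -0.10 (SE 0.32) and -0.03 (SE 0.21).

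**Figure D4:**
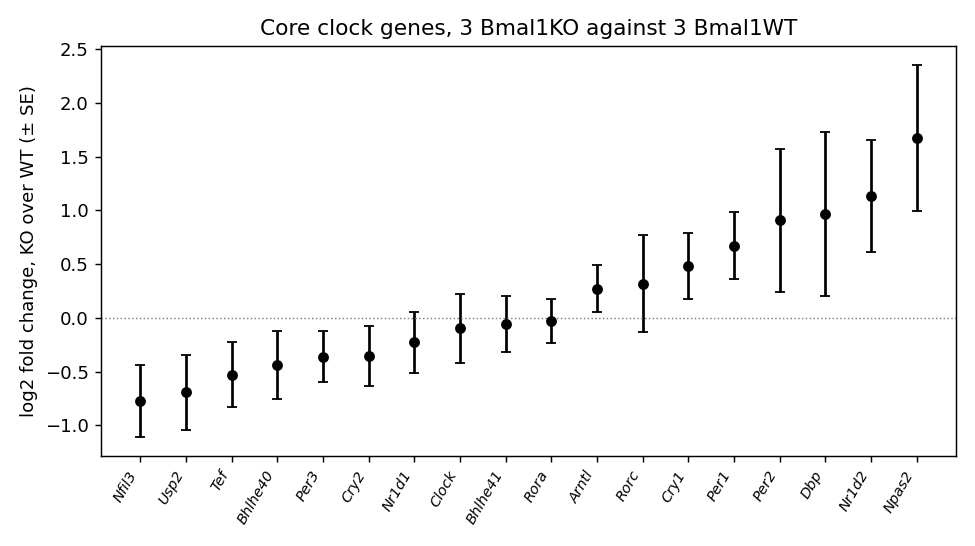
Log2 fold change of Bmal1KO over Bmal1WT with its standard error for the 18 tested core clock genes, ordered by fold change, from 3 libraries per group. Values run from -0.77 for Nfil3 to 1.68 for Npas2 with Arntl at 0.27, and none passed the test over all genes.

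The 28 tested lists that were not called had mean changes between -0.28 log2 units (erythroid genes, camera adjusted p = 0.18) and 0.82 (lymph node stroma, camera adjusted p = 0.112). Dendritic cell genes came closest to the threshold (0.49, 12 of 13 higher, camera adjusted p = 0.0559), with Clec9a past the test adjusted over the list alone. Adipose stromal, proliferation, matrix, interferon and MHC class II genes had camera adjusted p of 0.286, 0.163, 0.17, 0.347 and 0.29. Beside the clock list, mean, median and test differed in sign for skeletal muscle (mean 0.19, median -0.39), hypoxia (0.01, -0.15), thermogenic genes (0.11, -0.01) and lipid-associated macrophages (both 0.02 with a test direction of down).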

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

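The tests of RNA from another tissue, of epididymis and testis, and of a lower share of adipocytes were chosen only after the result was seen.

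In Bmal1KO replicate 1, 7672 genes carried counts that were 0 in the other 5 libraries, where 353 to 681 genes per library were alone in this way. They held 24648 counts, with at most 33 on a single gene. Olfactory receptor genes, of which the table lists 1408, had a count for 792 in this library, for 125 and 112 in Bmal1KO replicates 2 and 3, and for 36 to 46 in Bmal1WT. RNA of another tissue is argued against, since the top 1% of these genes held only 6.33% of their counts, where a few abundant transcripts were predicted to hold over 30%. Genomic DNA remained a candidate source. Over protein-coding genes at 0 in the other libraries, counts followed exonic length (Spearman's rho 0.38 across 3864 autosomal genes, which are not independent replicates) and lay between 0.594 and 1.07 per exonic kb on each of the 19 autosomes, but X carried only 0.33 times the autosomal density (95% bootstrap interval 0.243 to 0.430). A value under 0.75 was predicted for male tissue, though the interval also lies under the 0.5 that 1 X copy would give, and that gap was not accounted for. An even background of that density would hold 1.62% of the library, and no biological explanation was tested.

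In Bmal1WT replicate 1, Gpx5, a glutathione peroxidase secreted by the epididymis, had 2273 counts and 0 in each of the other 5 libraries. It was joined by Lcn8 (906 counts), Lcn9 (739), Defb20 (670), Rnase10 (640), Cst11 (390) and Adam7 (277), named after their values were seen. Epididymal tissue cut with the fat is a candidate source, since 13 of the 27 genes of the epididymis and testis list, which visceral fat is not known to use and of which 0 passed the expression filter, had at least 10 counts in this library. In each other library at most 1 of the 27 did. Testis is argued against: the abundant germ cell transcripts Prm1, Prm2 and Tnp1 had 0 counts together in this library. The list held 0.0713% of the library, and no biological explanation was tested.

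Immune cell lists were called higher and adipocyte and endothelial lists lower in Bmal1KO with camera's preset correlation, but 0 of the 17 called lists with an estimated correlation (smallest adjusted p = 0.675). A lower share of adipocytes alone would raise every other cell type alike. The endothelial list went against this prediction over its genes, with a median of -0.65 log2 units (95% bootstrap interval over genes -0.76 to -0.52). That interval leaves out the spread between libraries. The endothelial mean of Bmal1KO replicate 1 (-0.14) lay inside the Bmal1WT range (-0.43 to 0.52), so between samples the test does not settle this explanation. Gene length and GC content are argued against as the whole cause of these calls, since 14 of the 17 called lists were still called in the same direction after their trend was removed (99.7% of list members had values). That test also used the preset correlation, with which other splits of the libraries called 3 to 23 lists. It therefore covers the calls and does not show a difference between the groups. Lymphoid tissue in the Bmal1KO samples cannot be told apart from other sources by these lists: the B cell shift minus the T cell shift was -0.29, -2.58 and 1.02 log2 units in replicates 1 to 3, so that T cell genes were higher without B cell genes in replicate 2 and B cell genes were higher still in replicate 3. The genotype stays open as well, untested apart from the group comparison itself.

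The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. At an unadjusted p under 0.05 the real split gave 1290 genes and the highest other 1327, and 2 of the 10 splits gave as many as the real one. At an adjusted p under 0.05 the real split and the highest other gave 0, so that all 10 were as large. Of gene lists, the real split called 17 and the highest other 23, and 3 of the 10 gave as many. Every other split called at least 3 lists. The small p-values of camera with the preset correlation can therefore not be taken as error rates for the genotype. The split with the highest counts set Bmal1WT replicate 1 and Bmal1KO replicates 2 and 3 against the rest, which keeps Bmal1KO replicate 1 with Bmal1WT libraries. That library also lay inside or just above the Bmal1WT range on the adipocyte, endothelial and ribosomal lists. It lay outside that range with the other Bmal1KO libraries on the T cell, mast cell, cholesterol synthesis and fatty acid oxidation lists, and whether its label is right was not tested.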

How the results depend on the processing

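The removal of background, the trend on length and GC, and leaving out Bmal1WT replicate 1 and Bmal1KO replicate 1 together were tests chosen only after the result was seen. No result changed direction under any alternative run. Counts of single genes moved with DESeq2, without edgeR's filter and with libraries left out. DESeq2, with its own filter and so not a change of test alone, called 36 genes higher and 24 lower, 7 of them outside the filtered set. EdgeR without a filter on low counts called 108 higher and 78 lower, 40 of them outside the filtered set, and 17 lists lower. In that unfiltered fit the median log2 fold change of all genes was 0.45, against 0.02 with the filter. Camera compares a list with the other genes, so its calls there are relative to a raised median. The lower genes of that fit included Crisp1, with 67 counts in Bmal1WT replicate 1 and 0 in the other 5 libraries. Whether the test or the filter caused the DESeq2 calls was not tested. With 1 library left out, genes higher ranged from 0 to 46 and genes lower from 0 to 110. The highest of both came without Bmal1KO replicate 1, 6 higher genes, all of immunoglobulins or Jchain, came without Bmal1KO replicate 2, and 1 lower gene, Ndufs5-ps, without Bmal1WT replicate 1. Without both replicates numbered 1, 11 genes were higher and 50 lower. The other scalings, filter and threshold, voom and background removal gave 0 genes. Lists called higher ranged from 6 to 11 and lower from 8 to 12 with 1 library left out, and 11 were higher without Bmal1KO replicate 1. Of the 17 lists, 10 were called with each library left out: T cell, mast cell, ribosomal, adipocyte, endothelial, cholesterol, fatty acid oxidation, citrate cycle, lipogenesis and lipolysis. Macrophage, mesothelial, B cell, plasma cell, mural, oxidative phosphorylation and adipokine lists were lost without Bmal1WT replicate 2 or 3 or a Bmal1KO library. Camera with an estimated correlation and fry called 0 higher and 0 lower lists. Scaling by library size alone moved the median log2 fold change of all genes to 0.11, from 0.02, and ended the B cell and plasma cell calls. Without the filter the macrophage (adjusted p = 0.104) and plasma cell (adjusted p = 0.0536) calls were lost, with a prior count of 0.5 the B cell call (adjusted p = 0.0506), and after the removal of the length and GC trend the adipokine (adjusted p = 0.0792), B cell (adjusted p = 0.0569) and oxidative phosphorylation (adjusted p = 0.105) calls. Leaving out both replicates numbered 1 ended the B cell, plasma cell, mast cell and oxidative phosphorylation calls, and background removal kept all 17. The background was removed from Bmal1KO replicate 1 alone. Bmal1KO replicates 2 and 3 also had counts on more olfactory receptor genes (125 and 112) than Bmal1WT (36 to 46). A background in those libraries was not tested. Same-numbered libraries did not deviate together (correlations -0.07, 0.09 and -0.03), so the numbers were not taken to pair the samples. With the replicate number as a block 0 genes were called, and 11 lists higher and 10 lower. Arntl kept log2 fold changes of 0.07 to 0.43 and was never called (adjusted p = 0.589 to 0.934, edgeR, DESeq2 or limma). Of the values of the 20 named genes over 15 alternatives, 60 passed the threshold and 240 did not. Depth limits genes of a few CPM, such as Foxp3 and Il2ra.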

Other observations

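Inflammatory cytokine genes moved both ways in Bmal1KO. The list was not called by camera (mean 0.40 log2 units, adjusted p = 0.0726) but had adjusted p = 0.0221 by fry's mixed test, and adjusted over the list alone 5 genes rose and 2 fell, with 0 over all genes by edgeR. Ccl3, a chemokine of activated myeloid cells, went from 4.61 ± 1.39 CPM (SD, n = 3) to 13.6 ± 4.35 CPM (log2 fold change 1.56, SE 0.37), Nfkbiz from 8.13 ± 1.33 to 16.1 ± 3.53 CPM (0.98, SE 0.30) and Il1b, the gene of interleukin-1 beta, from 0.724 ± 0.611 to 3.79 ± 0.837 CPM (2.37, SE 0.75). The monocyte attractant Ccl7 fell from 139.7 ± 50.2 to 80.0 ± 10.5 CPM (-0.80, SE 0.24).

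Fry's mixed test also passed for cholesterol synthesis (adjusted p = 0.00888), skeletal muscle (adjusted p = 0.00888) and lymph node stroma (adjusted p = 0.0255). In the muscle list Ttn, the gene of the giant protein titin, had its highest value in Bmal1KO replicate 1. Ttn was at 1.47 ± 0.250 CPM (SD, n = 3) in Bmal1WT and 8.63 ± 9.89 CPM in Bmal1KO. Its values in Bmal1KO replicates 2 and 3 were 2.04 and 3.85 CPM. Bmal1KO replicate 1 is the library with a background that followed exonic length. How much of its Ttn value came from that background was not tested, so the Bmal1KO mean of Ttn is uncertain. Myl1 was at 30.6 ± 5.39 CPM in Bmal1WT and 18.1 ± 5.30 CPM in Bmal1KO. In the lymph node stroma list Mfge8, Ltb and Fcer2a rose and Clu fell with p adjusted over the list alone.

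Antibody and follicle transcripts set Bmal1KO libraries apart from each other. These genes were chosen after their values were seen. Igkc had 9918, 218 and 23796 counts in Bmal1KO replicates 1 to 3 and 473 to 1895 in Bmal1WT, and Jchain, which joins antibody units, was at 298, 4.08 and 586 CPM against 11.2 to 39.5 CPM. Cxcl13, the chemokine of B cell follicles, had 2349 counts in Bmal1KO replicate 3 and 96 to 291 in the other 5 libraries, and the B cell receptor Fcer2a 169 against 5 to 13.

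Among adipocyte genes, also chosen after their values were seen, Cfd (adipsin) was at 2393 CPM in Bmal1KO replicate 1, above the 1334.5 to 2216 CPM of Bmal1WT, and at 317 and 285 CPM in Bmal1KO replicates 2 and 3. Car3, a carbonic anhydrase, followed the same order, with 158543 counts in Bmal1KO replicate 1 against 54524 and 39800 in replicates 2 and 3. With all libraries in the fit neither gene passed edgeR's test (adjusted p = 0.798 for Cfd and 0.724 for Car3). Without Bmal1KO replicate 1, Cfd and Car3 passed it (adjusted p = 0.0018 and 0.0113). This is no independent evidence, since both were chosen after that library's values were seen.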
